A study of Mus musculus with 42 samples.

How the data were processed

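Messenger RNA was measured in livers of male C57B6/J mice by stranded libraries of enriched mRNA, sequenced as 100 bp paired ends on a DNBseq instrument, per the labels. The mice were given vehicle, corticosterone (CORT, the main glucocorticoid of mice), enzalutamide (ENZA, an antiandrogen drug) or both, in an acute and a chronic arm. The acute arm has 4 groups and the chronic arm 3, each of 6 mice, 42 libraries in all. A chronic group given enzalutamide alone was not analysed here. Doses, routes and days of treatment are not given in the sources used here.

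The deposited values are raw read counts per gene, 1 table per arm, not normalized and not pooled. Per the submitters' processing notes, the tools used before deposit were FastQC, MultiQC, STAR 2.7.3a and HTSeq 0.12.4 with genome build mm10 (GRCm38). The gene annotation release and the strand setting of HTSeq are not given in the sources used here, so antisense and overlapping genes are uncertain. Per the labels, RNA of the acute livers was extracted with a Qiagen kit and RNA of the chronic livers with a Macherey-Nagel NucleoSpin kit. The extraction kit therefore cannot be told apart from the duration, and levels are compared between arms only as effects against the vehicle or corticosterone group of the same arm.

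Each table holds 55573 gene IDs, of which 55394 were paired with a symbol and 55480 were found in GENCODE M21 on the same build, which gave the coordinates. A symbol is shared with another ID for 215 of the IDs. The 5 HTSeq summary lines that name no gene were left out of library sizes and tests. Reads aligned to several places made up 9.34 to 12.8% of the counted read pairs in acute libraries and 18.6 to 22.7% in chronic libraries. Unaligned pairs made up 2.5 to 9.97% and 3.11 to 8.51%, pairs in no gene 4.85 to 6.25% and 3.95 to 5.82%, and ambiguous pairs 2.07 to 2.85% and 1.9 to 2.47%, in the acute and chronic arm. Low-quality alignments made up at most 0.0198% and 0.136%.

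Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood model with robust spread was fitted to all libraries of an arm, with group means and no covariate. This left 13733 genes in the acute and 13099 in the chronic arm. Differences between the arms were tested as a difference of effects in 1 model of all 42 libraries and 14138 genes. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison and called at 0.05. A log2 fold change is given with its standard error as ± SE. Levels are given in CPM (counts relative to library size, scaled by TMM) as mean ± SD. The labels give each library as a separate mouse, and no repeated library was seen. Within a group, pairs of libraries differed by a chi-square of at least 10.1 per degree of freedom, and their log levels correlated at r 0.957 to 0.991.

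The 32 gene lists (22 pathways and 10 sets of cell type markers), the rule for named genes, the tests and the alternatives below were fixed before the data were examined, except where said. Named genes had an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the mice of both groups. The 8 with the largest fold change in each direction were taken, or 5 for a difference of effects, without predicted genes. To these were added up to 4 members of each list with the smallest p, and a few genes always, among them Nr3c1, Fkbp5, Tsc22d3, Per1 and Hsd11b1. Some are left out for length, and some are not reported here. Lists were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 107 list calls over all comparisons, 17 held with an estimated correlation. The male-biased, female-biased and CAR and PXR lists hold families of near-identical genes. For these lists and the named genes, the share of 50-base stretches of the longest transcript that also occur in another gene was computed, and a gene with 10% or more shared is called uncertain in the text. This share was extended from the lists to all named genes after their values had been seen.

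Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no low-count filter, a stricter filter (CPM of 1 in 6 libraries), a fit of only the groups compared, each library left out in turn, and sets of consecutive mouse numbers as a term. Of these, list calls were rerun only with RLE size factors and with no low-count filter. The mouse numbers in the labels do not repeat between groups. Taken in order, acute numbers fall into 6 sets with 1 mouse of each of the 4 groups, and chronic numbers into 6 sets of 3 mice of 1 group. The labels do not say that a number marks a batch. Deviations from the group means correlated at a mean r of 0.0584 within an acute set against -0.0103 for other pairs, and ranged from -0.149 to 0.272. In the chronic arm the mean was -0.00367 within a set of the same group against -0.312 for other pairs of the group. Within a set it ranged from -0.488 to 0.339. Deviations from a shared mean are negative on average by construction, so mice of a chronic set were more alike than other mice of their group. Fitted as a random effect, the chronic sets had a consensus correlation of 0.22. The main chronic tests treat each mouse as independent. The numbers were not taken to pair the mice. Leaving out acute vehicle mouse L19A, acute CORT+ENZA mouse L36A and chronic CORT+ENZA mouse 18 was added after their principal component scores had been seen, as were list tests without chronic vehicle mouse 11.

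The steps were tested on simulated counts with 200 genes changed among the real genes. Genes of the lowest levels were not among those changed. Counts were drawn independently, without sets of mice or mice that stand apart, so the shares below do not cover such structure. In the simulated acute comparison of 13733 genes, 61.2% of genes changed by 1.5 times were called, 88.1% at 2 times and 98.5% at 4 times, with 6 false among 171 calls. In the simulated chronic comparison of 13099 genes the shares were 61.2, 85.1 and 95.5%, with 7 false among 168 calls. Gene counts per library were 18674151 to 20464521 in the acute and 15381724 to 19581723 in the chronic arm.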

Results

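Liver mRNA was counted in 42 male mice to examine how glucocorticoid and androgen signalling interact. The acute arm held 6 mice each on vehicle, corticosterone (CORT), enzalutamide (ENZA) and CORT+ENZA. The chronic arm held 6 mice each on vehicle, CORT and CORT+ENZA. Libraries held 18674151 to 20464521 gene counts in the acute and 15381724 to 19581723 in the chronic arm, and 19033 to 20773 and 18127 to 19740 genes were detected. On the second principal component, which held 15% of the variance of the acute arm, vehicle mouse L19A (-45.2) and CORT+ENZA mouse L36A (-34.8) lay apart from the other acute mice (-18.3 to 21.5). In the chronic arm CORT+ENZA mouse 18 lay apart from its group on the first component, at -16 against 9.7 to 20.9, and so did vehicle mouse 11, at -10.3 against -41.6 to -34.6. Library shares were compared with the vehicle group of the same arm in 35 two-sided exact permutation tests (n = 6 per group). After Benjamini-Hochberg adjustment, the mitochondrial share was higher in acute ENZA (9.57 ± 0.81 against 7.77 ± 0.8%, exact p = 0.00433, adjusted p = 0.0303). The unaligned share was lower in chronic CORT (5.09 ± 1.3 against 7.45 ± 0.83%, exact p = 0.00433, adjusted p = 0.0303). The share of the 10 most abundant genes was lower in chronic CORT+ENZA (16.3 ± 0.92 against 20.4 ± 0.75%, exact p = 0.00216, adjusted p = 0.0252).

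The first comparison asked what acute CORT changes in the liver. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 3.09 ± 1.86 to 19.5 ± 3.52 CPM (mean ± SD, n = 6 per group). The gene (ENSMUSG00000023067) lies on chromosome 17 from 29090976 to 29100727 in GRCm38. Plin5 (ENSMUSG00000011305, chromosome 17, 56111601 to 56117596), a coat protein of lipid droplets, rose from 35.1 ± 10.5 to 94.6 ± 15 CPM (n = 6). Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a cochaperone of steroid receptors, rose from 86.1 ± 44.2 to 207 ± 26.2 CPM (n = 6). The B cell receptor genes Cd79a and Cd79b, the mineralocorticoid receptor gene Nr3c2 and the clock genes Per3 and Dbp fell. In all, edgeR called 222 of 13733 genes, 130 higher and 92 lower in CORT, and 52 of them changed by at least 1 on the log2 scale.

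Among the glucocorticoid-induced genes, 6 of 25 measured members rose with acute CORT, 7 adjusted over the list alone (camera adjusted p = 1e-09, and 0.0233 with an estimated correlation). As log2 fold changes ± SE, Cdkn1a rose by 2.65 ± 0.37 (adjusted p = 0.000303), the transcription factor gene Zbtb16 by 1.94 ± 0.35 (adjusted p = 0.00547) and Tsc22d3, the glucocorticoid-induced leucine zipper gene, by 0.83 ± 0.17 (adjusted p = 0.0092). Lpin1, a phosphatidate phosphatase gene of triglyceride synthesis, rose by 1.74 ± 0.27 (adjusted p = 0.00128) and Fkbp5 by 1.26 ± 0.24 (adjusted p = 0.00595). Of the lipid droplet genes, 2 of 14 rose, 2 adjusted over the list alone (camera adjusted p = 0.00067, and 0.0233 with an estimated correlation). These were Plin5, by 1.43 ± 0.16 (adjusted p = 1.91e-05), and Plin4, by 1.81 ± 0.28 (adjusted p = 0.000997). The B cell marker list had 4 of 6 members lower, 5 adjusted over the list alone (camera adjusted p = 1e-09, and 0.0233 with an estimated correlation). Log2 fold changes were -1.67 ± 0.27 for Cd79b, -1.54 ± 0.31 for Cd79a and -2.02 ± 0.44 for Fcer2a, the low-affinity IgE receptor gene (adjusted p = 0.0013, 0.00755 and 0.0153). Outside the lists, Fam107a rose by 3.13 ± 0.58 (adjusted p = 0.00595). Fnip2 fell by 1.04 ± 0.16, Sox5 by 0.96 ± 0.14, Eepd1 by 0.82 ± 0.11 and the phosphodiesterase gene Pde4c by 0.77 ± 0.16 (adjusted p = 0.000961, 0.000374, 0.000246 and 0.0092).

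In the other lists, few members passed the test with acute CORT. Nr3c2 fell by 0.81 ± 0.17 (adjusted p = 0.0124), 1 of 2 members of the steroid receptor and metabolism list that were lower among 15, with 2 adjusted over the list alone (camera adjusted p = 0.563). Per3 fell by 0.85 ± 0.14 and Dbp by 0.83 ± 0.17 (adjusted p = 0.0013 and 0.0092), the 2 members of the circadian clock list of 19 that were lower, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.312). No member of the gluconeogenesis list of 18 passed over all genes and 5 rose adjusted over the list alone (camera adjusted p = 0.00476), but the list had adjusted p = 0.723 with an estimated correlation and 0.23 without L19A and L36A, where the median was 0.09 in place of 0.18. Male-biased genes had a median of 0.53 and none of 23 passed, also adjusted over the list alone (camera adjusted p = 1.89e-07; adjusted p = 0.52 with an estimated correlation). Female-biased genes had a median of -1.09, with none of 17 past the test and 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00067; adjusted p = 0.541 with an estimated correlation). Of the NF-kappaB and chemokine genes, 1 of 13 was lower, 5 adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.619 with an estimated correlation). Interferon-stimulated genes had a median of -0.26 with none of 20 past the test and 1 lower adjusted over the list alone (camera adjusted p = 0.00511), with adjusted p = 0.74 with an estimated correlation and 0.17 without L19A and L36A, where the median was -0.16.

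The count of 222 was 419 with DESeq2, 356 with limma-voom and 96 when only the libraries of these groups were fitted, where Fkbp5 had adjusted p = 0.0734 and Fam107a 0.0695 (as low as 2.75e-05 and 0.000219 over the other settings). It was 137 without vehicle L25A, 138 without CORT L8A, 138 without CORT L26A and 135 without CORT L32A. Without L19A and L36A together it was 323, with 151 higher and 172 lower, so the majority turned from higher to lower.

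**Figure D1:**
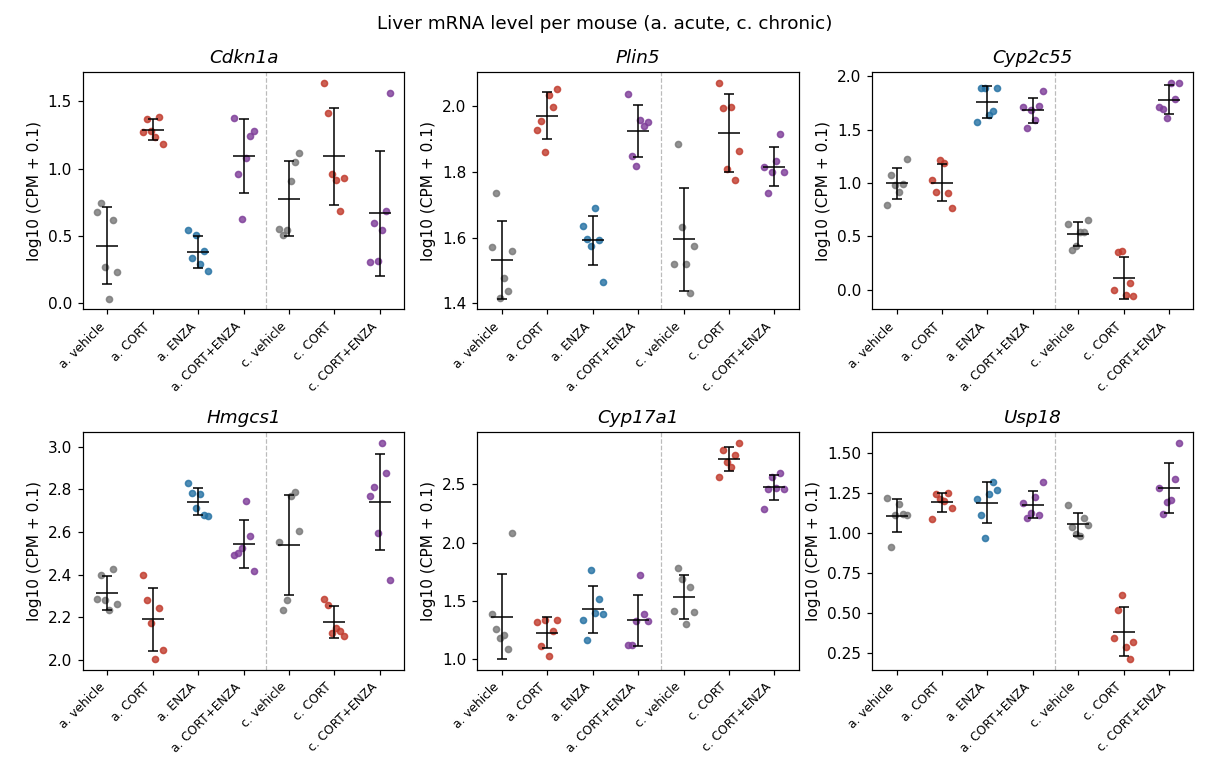
Level of 6 genes in each mouse, as log10 of CPM + 0.1, in the 7 groups (6 mice each); points are mice, bars are the mean ± SD of the log values, and a dashed line parts the acute (a.) from the chronic (c.) arm. Cdkn1a and Plin5 were higher in acute CORT than vehicle, Cyp2c55 and Hmgcs1 in acute ENZA than vehicle, and in chronic CORT Cyp17a1 was higher and Usp18 lower than in vehicle.

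Acute ENZA alone raised genes of drug metabolism and of cholesterol synthesis. Cyp2c55 (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693), a cytochrome P450 gene induced through the xenobiotic receptors CAR and PXR, rose from 10.3 ± 3.63 to 60.3 ± 19.5 CPM (n = 6). Cyp2c29 (ENSMUSG00000003053, chromosome 19, 39269405 to 39330713) rose from 1220 ± 243 to 3310 ± 425 CPM (n = 6). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), the cytosolic HMG-CoA synthase gene of sterol synthesis, rose from 209 ± 39.7 to 557 ± 81.1 CPM (n = 6). Of 13733 genes, 180 were called, 116 higher and 64 lower, 41 of them by at least 1 on the log2 scale.

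Of the CAR and PXR targets, 12 of 21 rose with acute ENZA, 19 adjusted over the list alone (camera adjusted p = 2.77e-44, and 6.53e-05 with an estimated correlation). Cyp2c55 rose by 2.55 ± 0.28, Cyp2c29 by 1.44 ± 0.14, and Nr1i2, which encodes PXR itself, by 0.6 ± 0.08 on the log2 scale (adjusted p = 1.21e-05, 9.81e-07 and 3.88e-05). Gstm3 (2.63 ± 0.42), Abcb1a (1.56 ± 0.27), the carboxylesterase gene Ces2a (1.05 ± 0.08) and, outside the list, Cyp3a59 (2.19 ± 0.31) rose too, but 28.8, 17, 22.2 and 28% of their sequence occurs in another gene and their values are uncertain (adjusted p = 0.00222, 0.00264, 2.64e-08 and 0.00065). Of the cholesterol synthesis genes, 13 of 21 rose, 19 adjusted over the list alone (camera adjusted p = 3.54e-46, and 0.00379 with an estimated correlation). Hmgcs1 rose by 1.41 ± 0.19, the sterol methyl oxidase gene Msmo1 by 1.21 ± 0.14 and the mevalonate kinase gene Mvk by 0.75 ± 0.12 (adjusted p = 0.000179, 1.62e-05 and 0.00222). The bile acid and steroid reductase gene Akr1d1 rose by 0.76 ± 0.15 (adjusted p = 0.0114). Foxa3, a hepatocyte transcription factor gene, fell by 0.85 ± 0.16 (adjusted p = 0.00711).

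Fatty acid synthesis genes had a median of 0.41 with acute ENZA, with 1 of 20 higher and 3 adjusted over the list alone (camera adjusted p = 0.00158; adjusted p = 0.559 with an estimated correlation). The median was 0.25 without L19A and L36A. Interferon-stimulated genes had 1 of 20 higher, 2 adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.612 with an estimated correlation). The member was Ddx58, the RIG-I gene, at 0.38 ± 0.08 (adjusted p = 0.0129), and the list median of 0.29 was 0.44 without L19A and L36A. Beside them, the Kupffer cell markers had a median of 0.26, with 10 of 10 above 0 and none past the test, also adjusted over the list alone (camera adjusted p = 0.196). ENZA mouse L29A lay above the mean of the other ENZA mice by 1.73 for the Kupffer, 1.27 for the T and NK and 1.84 for the neutrophil markers on the log2 scale, and had Irf7 at 130 CPM (37.7 to 68.6 in the others). Proliferation genes had a median of 0.33, none of 16 past the test and 2 higher adjusted over the list alone (camera adjusted p = 0.000271; adjusted p = 0.559 with an estimated correlation). Acute phase genes had a median of -0.41 and none of 20 past the test, also adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.685 with an estimated correlation). Male-biased genes (median -0.18, 1 of 23 lower, 1 adjusted over the list alone), pericentral hepatocyte genes (median -0.2, none of 13 past the test, 1 lower adjusted over the list alone) and erythroid markers (median -0.92, none of 5, 2 lower adjusted over the list alone) lay lower. Their camera adjusted p of 0.00569, 0.0145 and 0.0207 became adjusted p = 0.612, 0.559 and 0.559 with an estimated correlation, and 0.0835, 0.105 and 0.105 without L19A and L36A, where the medians were -0.09, -0.21 and -0.82.

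The count of 180 was 382 with DESeq2, 308 with limma-voom, 90 without the low-count filter and 94 when only these groups were fitted. It was 114 without vehicle L1A, 112 without vehicle L25A, 77 without ENZA L11A, 91 without ENZA L29A and 101 without ENZA L35A.

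Of the 23 genes that rose when ENZA was added to acute CORT, 20 had also risen with ENZA alone. Cyp2c55 stood at 10.7 ± 4.3 CPM in CORT and 49.5 ± 13.9 CPM in CORT+ENZA, and Hmgcs1 at 162 ± 54.8 and 360 ± 103 CPM (n = 6). Of 13733 genes 24 were called, 23 higher and 1 lower. CAR and PXR targets had 6 of 21 members higher, 13 adjusted over the list alone (camera adjusted p = 7.08e-53, and 1.38e-05 with an estimated correlation). Cyp2c55 rose by 2.21 ± 0.28, Cyp2c29 by 1.3 ± 0.14 and Cyp3a11, a classical PXR target, by 1.18 ± 0.2 on the log2 scale (adjusted p = 0.000162, 1.43e-05 and 0.0054). Cholesterol synthesis genes had 5 of 21 higher, 11 adjusted over the list alone (camera adjusted p = 3.77e-38, and 0.0112 with an estimated correlation). Hmgcs1 rose by 1.15 ± 0.19, Mvk by 0.74 ± 0.12 and Msmo1 by 0.79 ± 0.14 (adjusted p = 0.0054, 0.0054 and 0.00916). When only these groups were fitted, their adjusted p were 0.0907, 0.0563 and 0.074, and over the other settings they were as low as 3.67e-06, 2.63e-05 and 9.19e-05. Fdft1, the squalene synthase gene, rose by 0.85 ± 0.11 (adjusted p = 9.51e-05), an uncertain value since 10.9% of its sequence occurs in another gene. Proliferation genes had 1 of 16 higher, 3 adjusted over the list alone (camera adjusted p = 6.99e-05; adjusted p = 0.811 with an estimated correlation). Erythroid markers had a median of -1.04 with none of 5 past the test, also adjusted over the list alone (camera adjusted p = 0.00416; adjusted p = 0.623 with an estimated correlation). The glucocorticoid-induced list had a median of -0.11, none of 25 past the test and 1 higher adjusted over the list alone (camera adjusted p = 0.41). The comparisons with ENZA share no libraries, and independent lists would have 0.194 higher genes in common in place of 20 (Fisher's exact test, p = 1.06e-39, across genes, which are not independent). The count of 24 was 59 with DESeq2, 50 with limma-voom and 39 without L19A and L36A. It was 14 without CORT L20A and 15 without CORT L26A, CORT+ENZA L18A or CORT+ENZA L30A, each left out alone.

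The interaction asked whether ENZA changes the acute CORT response. EdgeR called 0 of 13733 genes, and 501 had an unadjusted p under 0.05, against 687 by chance. DESeq2 and limma-voom also called 0, with 645 and 680 at an unadjusted p under 0.05. Fasn, the fatty acid synthase gene, had an interaction of -0.78 ± 0.41 and Tsc22d3 of -0.69 ± 0.24 on the log2 scale (adjusted p = 0.994 for both). As lists, fatty acid synthesis (median -0.4), cholesterol synthesis (-0.26), interferon-stimulated (-0.21), CAR and PXR (-0.15) and periportal hepatocyte genes (-0.15) lay lower, and male-biased (0.26) and acute phase genes (0.6) higher. Their camera adjusted p were 2.93e-06, 1.97e-06, 0.0282, 0.00479, 0.0282, 0.00479 and 0.00199, no member passed over all genes or adjusted over the list alone, and all 7 had adjusted p = 0.726 with an estimated correlation. Without L19A and L36A, the cholesterol, male-biased and periportal lists had medians of -0.13, 0.22 and -0.01 (adjusted p = 0.0696, 0.0889 and 0.953), and the fatty acid and interferon lists of -0.26 and -0.47. Beside the interferon list, Kupffer cell markers had a median of -0.24, with 0 of 10 above 0, and T and NK markers of -0.6 over 3, none past the test, also adjusted over the list alone (camera adjusted p = 0.273 and 0.759). ENZA mouse L29A lay above the other ENZA mice by 1.73 and 1.27 for these markers on the log2 scale, with Irf7 at 130 CPM (37.7 to 68.6 in the others).

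Of the genes that CORT changed against vehicle, 57 were also higher and 25 also lower in CORT+ENZA than in ENZA, against 1.4 and 0.67 for independent lists. Against acute ENZA, CORT+ENZA mice had Cdkn1a higher by 2.56 ± 0.38, Plin5 by 1.11 ± 0.16, Plin4 by 1.68 ± 0.29 and Fkbp5 by 1.27 ± 0.24 on the log2 scale (adjusted p = 0.000881, 0.000384, 0.00266 and 0.00661). Scara5, a ferritin receptor gene, rose by 3.08 ± 0.39 and Errfi1, a feedback inhibitor gene of the EGF receptor, by 0.91 ± 0.18, while Eepd1 fell by 1.11 ± 0.11 and Rnf152 by 0.97 ± 0.12 (adjusted p = 0.000237, 0.00872, 5.29e-06 and 5.81e-05). Of 13733 genes, 248 were called, 148 higher and 100 lower. Glucocorticoid-induced genes had 8 of 25 higher, 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.71e-09, and 0.0274 with an estimated correlation). Lipid droplet genes had 3 of 14 higher, 3 adjusted over the list alone (camera adjusted p = 6.86e-05, and 0.0268 with an estimated correlation). Cholesterol synthesis had 2 of 21 lower, 11 adjusted over the list alone (camera adjusted p = 4.96e-11; adjusted p = 0.206 with an estimated correlation). Fatty acid synthesis had 2 of 20 lower, and 10 lower with 1 higher adjusted over the list alone (camera adjusted p = 1.51e-06; adjusted p = 0.206 with an estimated correlation). Male-biased genes had 3 of 23 higher, 15 adjusted over the list alone (camera adjusted p = 1.12e-16; adjusted p = 0.0762 with an estimated correlation). B cell markers had 3 of 6 lower, 4 adjusted over the list alone (camera adjusted p = 4.24e-07; adjusted p = 0.0762 with an estimated correlation). The unfolded protein response list had a median of 0.2, with none of 22 past the test, also adjusted over the list alone (camera adjusted p = 0.000944; adjusted p = 0.2 with an estimated correlation). Over the 222 genes called for CORT against vehicle, the fold change against ENZA followed that against vehicle with a slope of 0.78 (jackknife SE 0.09) and 98.6% had the same sign, in libraries that both comparisons do not share. The genes were chosen in the first comparison, which alone can lower the slope. The count of 248 was 442 with DESeq2, 634 with limma-voom and 156 without the low-count filter. It was 145 without ENZA L5A, 126 without ENZA L17A, 157 without ENZA L29A, 133 without ENZA L35A, 142 without CORT+ENZA L6A and 118 without CORT+ENZA L12A.

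In acute CORT+ENZA mice against vehicle, Cyp2b10, the classical CAR target, rose from 10.6 ± 7.98 to 90.8 ± 71.4 CPM (n = 6; log2 fold change 3.1 ± 0.6, adjusted p = 0.00725). Cyp2c55 rose by 2.26 ± 0.28, Nr1i2 by 0.79 ± 0.08, Msmo1 by 0.79 ± 0.14, Plin5 by 1.28 ± 0.16 and Cdkn1a by 2.19 ± 0.37 on the log2 scale (adjusted p = 7.24e-05, 5.64e-07, 0.00249, 5.66e-05 and 0.00179). Usp2, a deubiquitinase gene, rose by 0.88 ± 0.15, and Gclc, of glutathione synthesis, fell by 0.61 ± 0.13 (adjusted p = 0.00173 and 0.0113). Of 13733 genes, 339 were called, 195 higher and 144 lower. CAR and PXR targets had 10 of 21 higher, 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.56e-28, and 0.000974 with an estimated correlation). Cholesterol synthesis had 9 of 21 higher, 12 adjusted over the list alone (camera adjusted p = 1.12e-11; adjusted p = 0.252 with an estimated correlation), and glucocorticoid-induced genes 5 of 25 higher, 6 adjusted over the list alone (camera adjusted p = 9.37e-07; adjusted p = 0.0819 with an estimated correlation). B cell markers had 4 of 6 lower, 4 adjusted over the list alone (camera adjusted p = 6.81e-07; adjusted p = 0.0972 with an estimated correlation). The urea cycle list had a median of 0.13 and none of 7 past the test, also adjusted over the list alone (camera adjusted p = 0.0388), with adjusted p = 0.38 with an estimated correlation and 0.131 without L19A and L36A, where the median was 0.06. The count of 339 was 566 with DESeq2, 674 with limma-voom and 203 when only these groups were fitted. It was 221 without vehicle L1A, 218 without vehicle L25A and 207 without CORT+ENZA L24A.

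The chronic arm asked first what longer CORT treatment changes. Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), the estrogen sulfotransferase gene, rose from 0.221 ± 0.235 to 38.5 ± 25.8 CPM, and Cyp17a1 (ENSMUSG00000003555, chromosome 19, 46667165 to 46673172), a steroid hydroxylase gene, from 36.8 ± 15.9 to 533 ± 126 CPM (n = 6). Usp18 (ENSMUSG00000030107, chromosome 6, 121245906 to 121270917), an interferon-induced deISGylase gene, fell from 11.3 ± 1.99 to 2.44 ± 0.953 CPM (n = 6). Of 13099 genes, 2401 were called, 1184 higher and 1217 lower, and 615 changed by at least 1 on the log2 scale.

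Of the female-biased genes, 6 of 14 rose and 2 fell with chronic CORT, 7 and 2 adjusted over the list alone (camera adjusted p = 1.13e-07; adjusted p = 0.11 with an estimated correlation). On the log2 scale Cyp17a1 rose by 3.86 ± 0.27 (adjusted p = 5.17e-08). Cyp2c69 (5.92 ± 0.59) and Cyp2c40 (5.37 ± 0.52) rose too but are uncertain, with 54.8 and 72.1% of their sequence in other genes (adjusted p = 4.17e-06 and 3.46e-06). Male-biased genes had 3 of 23 higher and 7 lower, 3 and 9 adjusted over the list alone (camera adjusted p = 0.0459; adjusted p = 0.627 with an estimated correlation), and a median of -0.41 that was -0.31 without vehicle mouse 11 (adjusted p = 0.0547). Elovl3, a fatty acid elongase gene, fell by 1.2 ± 0.22 (adjusted p = 0.00117). Several major urinary protein genes fell, among them Mup18 by 5.4 ± 0.75 and Mup17 by 4.8 ± 0.97, while Mup20 rose by 1.2 ± 0.19 (adjusted p = 0.000112, 0.00268 and 0.000261), all uncertain with 89.6, 78.1 and 50.5% of their sequence in other genes. The growth hormone and IGF list had 1 of 15 higher and 4 lower, the same counts adjusted over the list alone (camera adjusted p = 0.0878). Its member Igfbp2 fell by 2.05 ± 0.22 and Ghr, the growth hormone receptor gene, by 0.48 ± 0.12 (adjusted p = 5.41e-06 and 0.00824).

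Interferon-stimulated genes had 15 of 20 members lower in chronic CORT, 17 adjusted over the list alone (camera adjusted p = 4.01e-15; adjusted p = 0.127 with an estimated correlation). Usp18 fell by 2.21 ± 0.26, the guanylate-binding protein gene Gbp3 by 2.16 ± 0.31 and Xaf1 by 1.44 ± 0.21 on the log2 scale (adjusted p = 1.45e-05, 9.81e-05 and 0.000101). Markers of some immune cells were lower in the same mice. B cell markers had 6 of 6 members lower, 6 adjusted over the list alone (camera adjusted p = 1.97e-08; adjusted p = 0.11 with an estimated correlation), with Cd79b at -3.33 ± 0.38 (adjusted p = 9.59e-06). Kupffer cell markers had 2 of 10 lower, 6 adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.627 with an estimated correlation), with a mean log2 CPM of 3.23 in vehicle mouse 11 against 4.37 to 5.01 in the other vehicle mice. Of the T and NK markers only Cd4 was measured, and it fell by 1.77 ± 0.35 (adjusted p = 0.0015). NF-kappaB and chemokine genes had 4 of 13 lower, 5 adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.627 with an estimated correlation). Sinusoidal endothelial (10 measured), cholangiocyte (5), neutrophil (3) and erythroid markers (5) had no member past the test, also adjusted over the list alone (camera adjusted p = 0.248, 0.903, 0.688 and 0.182). The cholangiocyte list had a median of 0.06 and a mean of 0.02 with a test direction downward. Stellate cell markers had 2 of 12 lower, 3 adjusted over the list alone (camera adjusted p = 0.0648, and 0.0432 without vehicle mouse 11). No pancreatic acinar marker was measured, and of the adipocyte markers only Car3, which fell by 2.5 ± 0.38 (adjusted p = 0.00023).

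CAR and PXR targets had 8 of 21 higher and 2 lower with chronic CORT, 11 and 2 adjusted over the list alone (camera adjusted p = 7.7e-07; adjusted p = 0.11 with an estimated correlation). Cyp2b10 (ENSMUSG00000030483, chromosome 7, 25897620 to 25926624) rose from 0.781 ± 0.367 to 57.8 ± 23.9 CPM (n = 6; log2 fold change 6.18 ± 0.37, adjusted p = 1.13e-08). Glucocorticoid-induced genes had 8 of 26 higher and 1 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 9.52e-05; adjusted p = 0.127 with an estimated correlation). Sult1e1 rose by 7.34 ± 0.72, Fkbp5 by 2.89 ± 0.4 and the transcription factor gene Cebpd by 1.28 ± 0.17 on the log2 scale (adjusted p = 3.95e-06, 0.000108 and 5.18e-05). Cholesterol synthesis had 10 of 21 lower and 1 higher, 13 and 1 adjusted over the list alone (camera adjusted p = 4.67e-05; adjusted p = 0.627 with an estimated correlation). Sqle, the squalene epoxidase gene, fell by 1.66 ± 0.33 and Sc5d by 1.25 ± 0.17 (adjusted p = 0.00236 and 4.67e-05). Fatty acid oxidation genes had 3 of 19 higher and 1 lower, 4 and 2 adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.627 with an estimated correlation), and their median of 0.23 was 0.43 without vehicle mouse 11, with 9 higher and 1 lower. Cyp4a14, a target of PPAR-alpha, rose by 3.98 ± 0.77 (adjusted p = 0.00184). In the steroid list of 15, 4 rose and 2 fell, 4 and 5 adjusted over the list alone (camera adjusted p = 0.612). Hsd11b1, whose enzyme regenerates active glucocorticoid, rose by 0.62 ± 0.12, and Serpina6, the corticosteroid-binding globulin gene, fell by 2.15 ± 0.22 (adjusted p = 0.00135 and 3.79e-06). Acute phase genes had 5 of 20 higher and 4 lower, 5 and 5 adjusted over the list alone, and a median of 0, a mean of -0.14 and a test direction upward (camera adjusted p = 0.343). The LPS-binding protein gene Lbp rose by 1.25 ± 0.14 (adjusted p = 7.96e-06). Asl and Arg1 of the urea cycle rose by 0.77 ± 0.1 and 0.56 ± 0.11 (adjusted p = 4.78e-05 and 0.00118). The count of 2401 was 952 with the sets of 3 mouse numbers as a random effect. No single library moved it by more than 1.5 times.

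**Figure D2:**
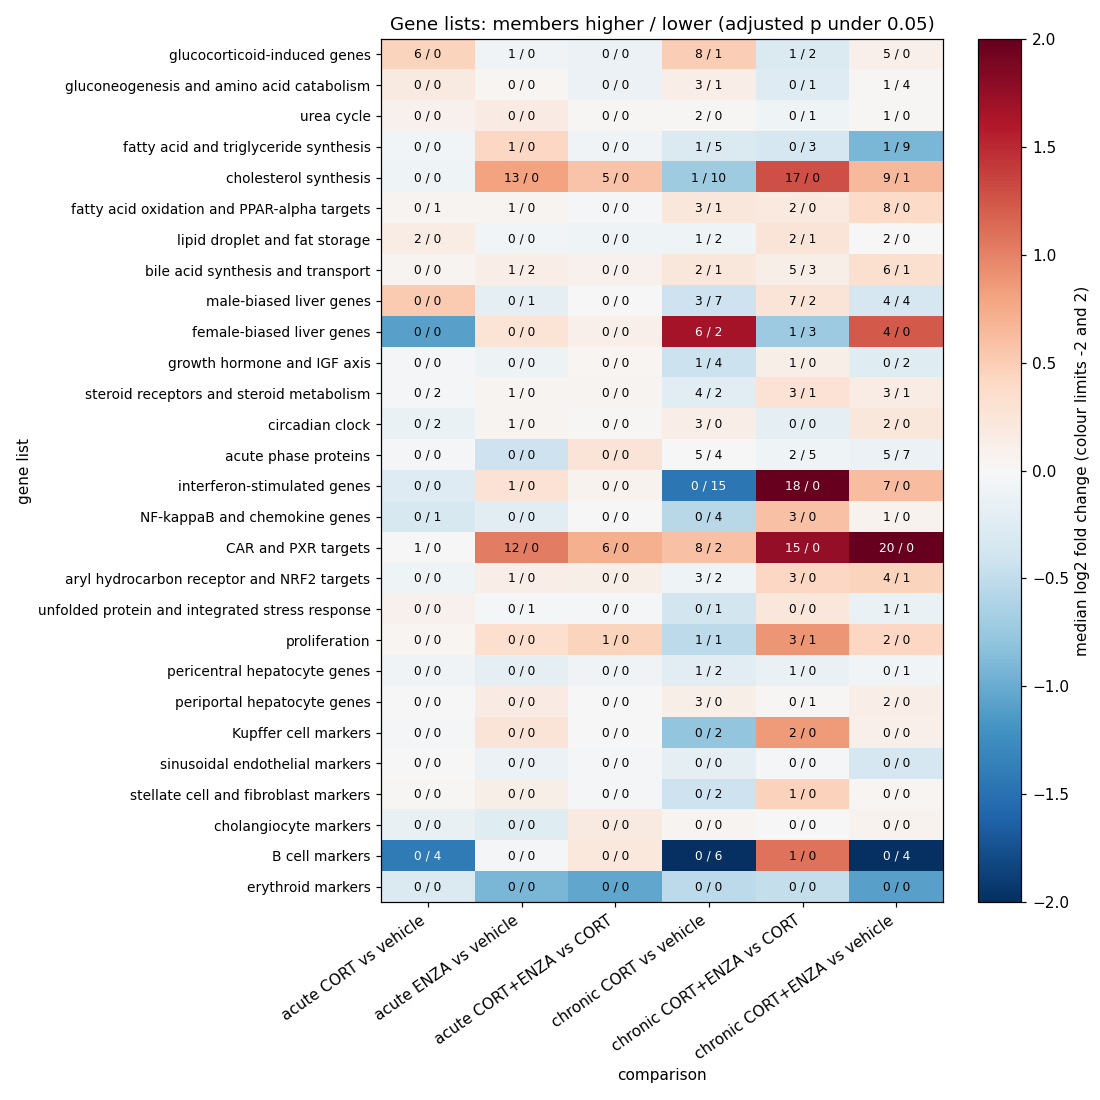
Median log2 fold change (colour, limits -2 and 2) of 28 gene lists in 6 comparisons, with the number of members higher / lower at an adjusted p under 0.05 in each cell. CAR and PXR targets had 12 of 21 members higher with acute ENZA and 15 when ENZA was added to chronic CORT, and interferon-stimulated genes had 15 members lower in chronic CORT and 18 higher when ENZA was added.

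The next comparison asked what ENZA changes when added to chronic CORT. Cyp2c55 rose from 1.32 ± 0.685 to 63 ± 20 CPM and Cyp2b10 from 57.8 ± 23.9 to 841 ± 221 CPM (n = 6). Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192) rose from 25.7 ± 6.21 to 157 ± 62.1 CPM, above the 81.1 ± 35.3 CPM of chronic vehicle (n = 6). Usp18 rose from 2.44 ± 0.953 to 20.1 ± 8.4 CPM, and Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), the interferon regulatory factor gene, from 13.2 ± 4.15 to 94.2 ± 44.6 CPM (n = 6). Of 13099 genes, 1552 were called, 916 higher and 636 lower, 451 of them by at least 1 on the log2 scale.

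Targets of CAR and PXR had 15 of 21 members higher, 18 adjusted over the list alone (camera adjusted p = 3.56e-52, and 1.16e-05 with an estimated correlation). On the log2 scale Cyp2c55 rose by 5.58 ± 0.29, Cyp2b10 by 3.86 ± 0.29, Cyp2c29 by 2.06 ± 0.11 and the transporter gene Abcc3 by 2.2 ± 0.17 (adjusted p = 7.46e-10, 1.25e-07, 7.46e-10 and 1.63e-07). Interferon-stimulated genes had 18 of 20 higher, 19 adjusted over the list alone (camera adjusted p = 2.51e-39, and 0.0172 with an estimated correlation). Usp18 rose by 3.04 ± 0.26, Irf7 by 2.83 ± 0.26, Ifit1 by 2.87 ± 0.32 and Xaf1 by 2.17 ± 0.21 (adjusted p = 4.28e-07, 1.37e-06, 1.55e-05 and 1.24e-06). Beside them, Kupffer cell markers had 2 of 10 higher, 6 adjusted over the list alone (camera adjusted p = 0.00877; adjusted p = 0.648 with an estimated correlation). B cell markers had 1 of 6 higher, 2 adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.635 with an estimated correlation), and stellate cell markers 1 of 12, 6 adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.677 with an estimated correlation). CORT+ENZA mouse 18 had the highest mean log2 CPM of the Kupffer markers in the chronic arm (5.86) and of the interferon-stimulated genes (4.93). Without it, the Kupffer median of 0.85 was 0.45 (adjusted p = 0.0404), the B cell list had a median of 1.12 in place of 1.09 and the stellate list of 0.22 in place of 0.46 (adjusted p = 0.0655 and 0.283). Cholesterol synthesis had 17 of 21 higher, 19 adjusted over the list alone (camera adjusted p = 9.83e-20; adjusted p = 0.114 with an estimated correlation). Sqle rose by 2.61 ± 0.34, Msmo1 by 2.16 ± 0.3 and Cyp51 by 1.73 ± 0.26 (adjusted p = 7.55e-05, 0.00012 and 0.000232).

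Female-biased genes had 3 of 14 lower and 1 higher when ENZA was added to chronic CORT, 4 and 3 adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.597 with an estimated correlation, and 0.0679 without the low-count filter). The uncertain Cyp2c69 and Cyp2c40 fell by 4.6 ± 0.52 and 3.66 ± 0.46 on the log2 scale, and the male-biased Cyp4a12a and Cyp4a12b, of which 48.9 and 49.4% is shared, rose by 1.62 ± 0.22 and 2.14 ± 0.24 (adjusted p = 2.35e-05, 6.55e-05, 9.45e-05 and 1.3e-05). Glucocorticoid-induced genes had 1 of 26 higher and 2 lower, 1 and 3 adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.597 with an estimated correlation). For Fkbp5, every CORT+ENZA mouse (81.3 to 151 CPM) lay below every CORT mouse (163 to 314 CPM). The main fit shares its spread with the vehicle mice. These parted by set of mouse numbers, at 42.7 to 66 CPM in mice 10 to 12 and 9.98 to 15.3 CPM in mice 13 to 15. Fkbp5 had a log2 fold change of -1.01 ± 0.37 (adjusted p = 0.0853), with adjusted p = 0.0236 by limma-voom and 0.00143 when only these groups were fitted, and up to 0.189 over the other settings. The glucocorticoid receptor gene Nr3c1 had 0.15 ± 0.08 (adjusted p = 0.253). Fatty acid synthesis genes had 3 of 20 lower, 3 adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.635 with an estimated correlation), among them the pyruvate kinase gene Pklr, which fell by 1.2 ± 0.25 (adjusted p = 0.00361). The gluconeogenesis list had 1 of 18 lower, 1 adjusted over the list alone (camera adjusted p = 0.0239), with adjusted p = 0.597 with an estimated correlation and 0.125 without mouse 18, where the median was -0.2 in place of -0.26. Its member Fbp1, fructose-1,6-bisphosphatase, fell by 0.68 ± 0.08 (adjusted p = 1.01e-05). Bile acid genes had 5 of 15 higher and 3 lower, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.635 with an estimated correlation), and their median of 0.12 was 0.23 without mouse 18. Cyp8b1, which sets the share of cholic acid, fell by 2.98 ± 0.65 (adjusted p = 0.00643). AhR and NRF2 targets had 3 of 10 higher, 4 adjusted over the list alone (camera adjusted p = 0.00877; adjusted p = 0.0748 with an estimated correlation), and their median of 0.41 was 0.21 without mouse 18. Among acute phase genes Orm3 rose by 2.77 ± 0.33 and Apcs, serum amyloid P, fell by 1.16 ± 0.13 (adjusted p = 2.07e-05 and 1.38e-05). Igfbp2 rose by 1.59 ± 0.22, Serpina6 by 0.91 ± 0.21 and the cyclin D1 gene Ccnd1 by 2.53 ± 0.34, and Hsd11b1 fell by 0.56 ± 0.12 (adjusted p = 8.02e-05, 0.00983, 9.26e-05 and 0.0045). Outside the lists, the angiopoietin-like gene Angptl8 fell by 2.28 ± 0.42, Wfdc2 by 2.47 ± 0.27 and Scara5 by 2.27 ± 0.37 (adjusted p = 0.00204, 9.48e-06 and 0.000513). The count of 1552 was 479 with the sets of 3 mouse numbers as a random effect, and no single library moved it by more than 1.5 times.

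**Figure D3:**
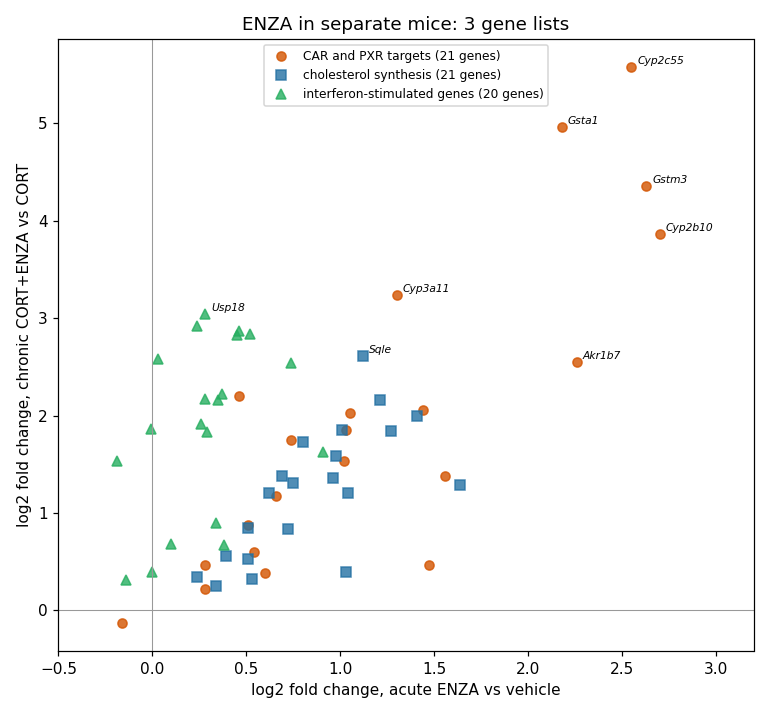
Log2 fold change of the members of 3 gene lists with acute ENZA against vehicle (x axis) and with ENZA added to chronic CORT (y axis); each point is a gene, and both comparisons use separate mice. On each axis 20 of 21 CAR and PXR targets lay above 0, with 12 (x) and 15 (y) past the test, and 21 of 21 cholesterol synthesis genes, with 13 and 17 past it (on the y axis, adjusted p = 0.114 with an estimated correlation), while the interferon-stimulated genes had a median of 0.29 on the x axis and 2.04 on the y axis.

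Of the genes tested in both arms, 63 were higher and 18 lower both with acute ENZA and when ENZA was added to chronic CORT, against 8.16 and 2.98 for independent lists, and 0 were opposite, against 5.67 and 4.29. These comparisons share no mice (Fisher's exact test across genes, p = 3.37e-42 and 3.63e-10). For CORT against vehicle, 52 genes were higher and 18 lower in both arms, against 11 and 8.31 (Fisher's exact test across genes, p = 2.86e-23 and 0.00128), and 2 and 5 were opposite, against 11.3 and 8.08.

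Against vehicle, chronic CORT+ENZA mice had 20 of 21 CAR and PXR targets higher, 21 adjusted over the list alone (camera adjusted p = 3.39e-65, and 3.64e-06 with an estimated correlation). Cyp2b10 rose by 10.04 ± 0.4, Akr1b7 by 5.34 ± 0.41 and Cyp2c55 by 4.24 ± 0.26 on the log2 scale (adjusted p = 1.33e-11, 4.6e-08 and 3.41e-09). Female-biased genes had 4 of 14 higher, 6 adjusted over the list alone (camera adjusted p = 0.000646; adjusted p = 0.401 with an estimated correlation). Interferon-stimulated genes, which were lower with CORT alone, had 7 of 20 higher, 7 adjusted over the list alone (camera adjusted p = 0.000505; adjusted p = 0.711 with an estimated correlation). Their median of 0.62 was 0.18 without CORT+ENZA mouse 18 (adjusted p = 0.0198, 7 higher), whose mean log2 CPM was 4.93 for these genes and 5.86 for the Kupffer cell markers. The Kupffer list had a median of 0.1 and none of 10 past the test, also adjusted over the list alone (camera adjusted p = 0.943). B cell markers had 4 of 6 lower, 5 adjusted over the list alone (camera adjusted p = 0.000505; adjusted p = 0.401 with an estimated correlation). Fatty acid synthesis had 9 of 20 lower and 1 higher, 12 and 2 adjusted over the list alone (camera adjusted p = 0.000628; adjusted p = 0.711 with an estimated correlation), where Elovl5 fell by 1.42 ± 0.21 and Scd1, stearoyl-CoA desaturase, by 1.48 ± 0.28 (adjusted p = 8.35e-05 and 0.00116). Fatty acid oxidation had 8 of 19 higher, 10 adjusted over the list alone (camera adjusted p = 0.000505; adjusted p = 0.711 with an estimated correlation), and a median of 0.39 that was 0.7 without vehicle mouse 11. The fatty acid transporter gene Cd36, of the lipid droplet list, rose by 1.62 ± 0.24 (adjusted p = 0.000108). Nqo1, an NRF2 target, rose by 1.31 ± 0.17, the fibrinogen gene Fgg fell by 0.84 ± 0.1 and Cyp8b1 by 4.57 ± 0.69 (adjusted p = 2.28e-05, 5.29e-06 and 0.000168). Fkbp5 rose by 1.88 ± 0.38 (adjusted p = 0.00232). Of 13099 genes, 2434 were called, 1348 higher and 1086 lower. The count was 3856 with limma-voom and 1201 with the sets of 3 mouse numbers as a random effect.

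Over the 2401 genes called for chronic CORT, the change when ENZA was added ran against the CORT change, with a slope of -0.34 (jackknife SE 0.05). No chronic group given ENZA alone was analysed, so an effect of ENZA itself cannot be told apart from a change of the CORT response. The CORT libraries were split so that both fold changes shared none, over 20 splits with slopes of -0.42 to -0.26, and 74.4% of the genes had opposite signs. Those genes were called from all CORT libraries, the ones behind both fold changes included. When the genes were called from a part of the CORT libraries, the slope was -0.27. There the CORT change came from the same libraries as the call, and only the added ENZA change from the rest. This choice of genes alone can bring the slope nearer to 0. Among the called genes, 229 rose with CORT and fell with ENZA, against 57.5 for independent lists, and 335 fell and then rose, against 85.1. Both comparisons use the CORT mice, so unchanged groups alone gave a correlation of -0.5 across genes in simulation, against -0.45 observed, and a covariance of -0.0223 against -0.098. With the CORT mice split, 161 genes moved in opposite directions against 35. The fold change of CORT+ENZA against vehicle contains the CORT change and the added ENZA change, so it is not a separate result. It had a slope of 0.61 on that of CORT (0.53 to 0.71 over 20 splits of the vehicle mice). In both, 609 genes were higher and 469 lower, against 122 and 101 for independent lists. The correlation was 0.64 against 0.51 in simulation and the covariance 0.161 against 0.0227, and with the vehicle mice split 466 genes moved the same way against 88.

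The last comparisons asked where the effects differ between the arms, each against its own controls, since kit and duration go together. The CORT effect differed for 873 of 14138 genes, 528 more positive and 345 more negative in the chronic arm. The female-biased list had 7 of 17 members more positive, 10 adjusted over the list alone (median 2.72, camera adjusted p = 1.12e-11, and 0.0257 with an estimated correlation). The log2 difference was 4.85 ± 0.62 for Cyp17a1 and 4.86 ± 0.8 for Cyp2b10 (adjusted p = 4.3e-06 and 0.000166). It was -2.44 ± 0.31 for Usp18, -1.87 ± 0.3 for Igfbp2 and -1.39 ± 0.3 for Serpina6 (adjusted p = 2.47e-06, 7.69e-05 and 0.00316). Male-biased genes had 8 of 24 more negative and 1 more positive, 10 and 1 adjusted over the list alone (camera adjusted p = 1.93e-07; adjusted p = 0.281 with an estimated correlation), and interferon-stimulated genes 9 of 20 more negative, 14 adjusted over the list alone (camera adjusted p = 2.24e-11; adjusted p = 0.203 with an estimated correlation). The circadian clock list had a median of 0.35 and none of 19 past the test, also adjusted over the list alone (camera adjusted p = 0.0299; adjusted p = 0.416 with an estimated correlation). T and NK markers had 1 of 5 more negative, 2 adjusted over the list alone (camera adjusted p = 0.00383; adjusted p = 0.247 with an estimated correlation). B cell markers had 3 of 7 more negative, 6 adjusted over the list alone (camera adjusted p = 1.8e-05; adjusted p = 0.203 with an estimated correlation), and stellate cell markers 1 of 12, 2 adjusted over the list alone (camera adjusted p = 0.00383; adjusted p = 0.416 with an estimated correlation). Kupffer cell markers had a median of -0.72 and none of 10 past the test, also adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.687 with an estimated correlation). The effect of adding ENZA to CORT differed for 179 genes, 128 more positive and 51 more negative in the chronic arm. Interferon-stimulated genes had 14 of 20 more positive, 18 adjusted over the list alone (camera adjusted p = 3.26e-51, and 0.000557 with an estimated correlation), with Usp18 at 3.04 ± 0.31, Irf7 at 2.68 ± 0.33 and Xaf1 at 1.9 ± 0.27 (adjusted p = 4.58e-08, 3.38e-06 and 1.46e-05). Beside them, markers of other cells had no member past the test. Kupffer cell markers had a median of 0.83 over 10, with none adjusted over the list alone (camera adjusted p = 0.00139; adjusted p = 0.478 with an estimated correlation). T and NK markers had 1.74 over 5, with 2 higher adjusted over the list alone (camera adjusted p = 0.0477; adjusted p = 0.476 with an estimated correlation). The B cell list had 0.91 over 7, with 1 higher adjusted over the list alone (camera adjusted p = 0.0235; adjusted p = 0.476 with an estimated correlation). Stellate cell markers had 0.31 over 12, with 1 higher adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.476 with an estimated correlation). Without L19A, L36A and 18 the Kupffer, T and NK and stellate medians were 0.39, 1.02 and 0.17 (adjusted p = 0.072, 0.235 and 0.192), and that of the interferon-stimulated genes 1.76. Targets of CAR and PXR had 7 of 21 more positive, 11 adjusted over the list alone (camera adjusted p = 1.7e-18, and 0.0013 with an estimated correlation), with Cyp2c55 at 3.34 ± 0.42 and Abcc3 at 1.89 ± 0.22 (adjusted p = 3.38e-06 and 2.83e-07). The count of 873 was 509 without the low-count filter, 1683 with limma-voom and 1436 without L19A, L36A and 18, and the count of 179 was 310 with DESeq2, 460 with limma-voom and 286 without these libraries. No single library moved either by more than 1.5 times.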

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

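The tests of immune cell content, of reads shared between paralogs and of acute mice L19A and L36A were chosen only after the result was seen. Levels and library shares were searched in 105 groups of 6 mice for a mouse far from the others. This found 13, where chance gives about 1 in 20 groups, or 5. Cyp17a1 stood at 120 CPM in acute vehicle mouse L31A (12.1 to 24.1 in the others) and at 52.2 CPM in acute CORT+ENZA mouse L24A (13 to 24.4). Sult1e1 stood at 0.416 CPM in acute ENZA mouse L29A (0 to 0.155), at 0.534 CPM in acute CORT+ENZA mouse L30A (0.0545 to 0.159) and at 0.69 CPM in chronic vehicle mouse 15 (0.0572 to 0.207). Irf7 stood at 130 CPM in acute ENZA mouse L29A (37.7 to 68.6). In acute CORT+ENZA mouse L36A the mitochondrial share was 11.5% (8.06 to 9.25) and Fkbp5 stood at 130 CPM (174 to 195). Among chronic vehicle mice, Plin5 stood at 76.8 CPM in mouse 11 (26.9 to 42.9) and Cyp2b10 at 1.49 CPM in mouse 15 (0.458 to 0.772). Chronic CORT+ENZA mouse 18 had Cdkn1a at 36.5 CPM (1.92 to 4.71), Usp18 at 36.2 CPM (12.9 to 21.5) and Irf7 at 182 CPM (61.9 to 88.7).

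The CORT effect differed between the chronic and the acute arm for 873 genes, by a test of the difference itself. Chronic minus acute, the log2 differences were 6.63 for Cyp2c69, 5.93 for Sult1e1, 5.81 for Cyp2c40 and 5.01 for Myom3. They were -7.19 for Mup-ps20, -6.29 for Mup18, -6.23 for Mup15, -5.59 for Mup17 and -5.46 for Cib3. The call of Sult1e1 was lost without acute vehicle L1A (adjusted p = 0.0748), L7A (0.055), L25A (0.124) or L31A (0.0741), in a range of 3.33e-07 to 0.124 over its alternatives. The list medians were 2.72 for female-biased genes and -4.32 for the 2 adipocyte markers measured. The effect of ENZA added to CORT differed for 179 genes. Its differences were 4.05 for Ly6d, 4.03 for Gbp10, 3.34 for Cyp2c55, 3.09 for Selenbp2 and 3.04 for Usp18. They were -5.5 for Obp2a, -4.13 for Cyp2c69, -3.31 for Cyp2c40, -2.73 for Wfdc2 and -2.5 for Scara5. The call of Ly6d was lost without acute CORT L26A (adjusted p = 0.0648), in a range of 0.000152 to 0.179 over its alternatives. The list medians were 1.95 for interferon-stimulated genes and 0.73 for CAR and PXR targets. Cyp2c69, Cyp2c40, Mup18, Mup15, Mup17, Gbp10, Selenbp2 and Obp2a are uncertain, with 54.8, 72.1, 89.6, 100, 78.1, 82.5, 52 and 11.7% of their 50-base stretches in another gene. Outside the gene counts, ambiguous read pairs made up 2.29% in chronic CORT and 2.23% in chronic CORT+ENZA mice, against 1.97% in vehicle (exact permutation p = 0.00216 for both, adjusted p = 0.0252 over 35 tests).

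Interferon-stimulated genes were lower in chronic CORT than vehicle and higher in chronic CORT+ENZA than CORT. As a list, the fall was not called with an estimated correlation, while the rise was. A change of immune cell content is a candidate explanation. In vehicle, CORT and CORT+ENZA, the Kupffer genes Clec4f and Cd5l stood at 62.7, 41 and 63.5 CPM and at 65.8, 32.1 and 80.6 CPM. Most Kupffer markers did not pass the test over all genes in either comparison. Cd4, at 2.81, 0.818 and 0.497 CPM, was lower with CORT but did not rise again with ENZA, unlike the interferon-stimulated genes. Cd4 does not stand for its list. The mean log2 CPM of all listed T and NK markers, mostly under the low-count filter, was -1.16 to -0.82 in vehicle. It was -2.52 to -1.93 in CORT and -2.22 to -0.28 in CORT+ENZA, where mouse 18 was highest. The means of 10 Kupffer and 6 B cell markers were used as covariates. With them, the median in CORT+ENZA against CORT kept 0.8 (SE 0.17) of its size, with 16 of 20 genes called (camera adjusted p = 7.85e-29). As far as these means track cell content, this argues against these cells as the whole cause of that part. A bound from the marker medians cannot decide, as its difference is close to its SE. Without covariates, the interferon median in CORT+ENZA against CORT lay 0.94 (SE 0.8, and 0.22 without CORT mouse 26) above the highest median of the Kupffer, B cell and neutrophil markers. T and NK cells stay open there, since only 1 of 10 of their markers passed the low-count filter (with Kupffer and T and NK covariates it kept 0.77, SE 0.21, with 15 called and camera adjusted p = 8.62e-32), and in CORT against vehicle, where it kept 0.5 (SE 0.58, 3 called) with the latter and 0.79 (SE 0.22, 1 called) with Kupffer and B cell covariates, immune cell content cannot be told apart from the treatment, because the B cell means of the groups do not overlap. A single library is argued against, since the medians kept at least 0.85 of their size without any 1 mouse, and an effect of the treatments within hepatocytes stays open, untested.

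Female-biased genes had 6 of 14 members higher and 2 lower in chronic CORT than vehicle, 7 and 2 adjusted over the list alone, with a mean log2 fold change of 2.17 (camera adjusted p = 1.13e-07; adjusted p = 0.11 with an estimated correlation). Over the 9 members with under 10% of their 50-base stretches in another gene the mean was 1.73, a ratio of 0.8 (SE 0.53 over members), and 3 of them were higher and 2 lower. Their mean leans on a few large values, while Tox, Prom1 and Nipal1 lay at 0.29, 0.01 and -0.19. Reads shared between paralogs therefore cannot be told apart from a change of the genes themselves, because the unshared members are few and go both ways. A single library is argued against, since the list mean kept at least 0.9 of its size without any 1 mouse. An effect of CORT on this sex-biased group stays open, untested.

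Acute vehicle mouse L19A and acute CORT+ENZA mouse L36A stood apart from the other 22 acute mice. Transcript length bias is a candidate explanation, since their deviations correlated with exon length across genes at -0.28 and -0.35, outside the -0.19 to 0.19 of the others. GC content bias is argued against, at 0.21 in both and inside -0.37 to 0.38. RNA from bile duct cells is another candidate source, since 1 marker list, the 6 cholangiocyte genes, lay outside the others (-0.84 to 0.64) in both, at 1.25 and 0.7, with Spp1 at 104 CPM in L19A (22.2 to 47.8 in its group) and 48.5 in L36A (15.7 to 46.1), while Sox9, at 9.32 (5.98 to 10.9) and 7.14 CPM (8.29 to 10.9), was not above its group in either. The mice belong to different groups, and no explanation beyond these was tested.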

How the results depend on the processing

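The tests without L19A and L36A, without these and chronic mouse 18, of the lists without chronic vehicle mouse 11, and over genes called from part of the libraries were chosen only after the data were seen. Of 473 results for named genes, 315 kept their direction and side of the threshold under every alternative run. Of 107 list calls, 17 held under every alternative run for lists, which were fewer. List calls were not rerun with DESeq2, limma-voom, sets of mouse numbers, only the groups compared or each library left out. An estimated correlation ended 90 list calls and left 17, leaving out the libraries that stood apart ended 18, RLE size factors 4, no low-count filter 2 and leaving out vehicle mouse 11 ended 1. Calls of named genes were lost for 78 without the low-count filter, 70 with sets of 3 mouse numbers, 53 with only the groups compared, 22 with limma-voom, 20 without L19A and L36A, 8 with sets of 6 mouse numbers and 1 without these libraries and mouse 18. Leaving out each library in turn lost 657 calls, counted gene by library, for 106 of the results. With DESeq2 the counts were 419 for acute CORT, 382 for acute ENZA, 59, 442 and 566 for acute CORT+ENZA against CORT, ENZA and vehicle, and 310 for the difference in the added ENZA effect. With limma-voom they were 356, 308, 50, 634 and 674 in the same acute comparisons, 3856 for chronic CORT+ENZA against vehicle, and 1683 and 460 for the differences in the CORT and the added ENZA effect. Without the low-count filter they were 90 for acute ENZA, 156 for acute CORT+ENZA against ENZA and 509 for the difference in the CORT effect. With only the groups compared, which leaves fewer libraries to estimate the spread, they were 96 for acute CORT, 94 for acute ENZA and 203 for acute CORT+ENZA against vehicle. With sets of 3 consecutive mouse numbers as a random effect they were 952 for chronic CORT, and 479 and 1201 for chronic CORT+ENZA against CORT and vehicle. Without L19A and L36A acute CORT+ENZA against CORT had 39 genes, and without these and mouse 18 the differences had 1436 and 286. Without 1 library, acute CORT ranged from 135 to 323, acute ENZA from 77 to 156, and acute CORT+ENZA from 14 to 22 against CORT, 118 to 253 against ENZA and 207 to 413 against vehicle. No library moved the other counts by over 1.5 times: 0 for the interaction, 1842 to 2761 for chronic CORT, 1136 to 1529 and 1960 to 2943 for chronic CORT+ENZA against CORT and vehicle, and 659 to 1104 and 141 to 208 for the differences. The slope of the added ENZA effect on the chronic CORT effect was -0.34, and -0.27 over genes called from part of the CORT libraries. Apart from the smaller number of libraries, the cause was not tested.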

Other observations

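Of the tests in this part, the splits of whole sets of chronic mice were chosen only after the result was seen. In acute CORT+ENZA mice against ENZA, interferon-stimulated genes had 3 of 20 members lower, 9 adjusted over the list alone (camera adjusted p = 5.06e-08; adjusted p = 0.233 with an estimated correlation). Ifi44 fell by 0.78 ± 0.17 on the log2 scale (adjusted p = 0.0156). Beside them, Kupffer cell markers had a median of -0.29, with 0 of 10 above 0 and none past the test, also adjusted over the list alone (camera adjusted p = 0.166), and T and NK markers a median of -1.01, with none of 3 past the test and 2 lower adjusted over the list alone (camera adjusted p = 0.193). ENZA mouse L29A lay above the other ENZA mice by 1.73 for the Kupffer markers on the log2 scale and had Irf7 at 130 CPM (37.7 to 68.6 in the others). Acute phase genes had 1 of 20 higher, 7 adjusted over the list alone (camera adjusted p = 9.98e-06; adjusted p = 0.418 with an estimated correlation). Female-biased genes had 2 of 17 lower, 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.418 with an estimated correlation). C6, which encodes a complement component, rose by 1.06 ± 0.22 (adjusted p = 0.0129).

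In chronic CORT mice against vehicle, Myom3 rose by 4.67 ± 0.33 on the log2 scale (adjusted p = 5.17e-08) and Cib3 fell by 5.8 ± 0.67 (adjusted p = 1.46e-05). Cp, which encodes ceruloplasmin, rose by 0.72 ± 0.09 (adjusted p = 1.41e-05), and Rrm2, which encodes a ribonucleotide reductase subunit, by 0.91 ± 0.15 (adjusted p = 0.000392). Bile acid genes had 2 of 15 higher and 1 lower, 4 and 2 adjusted over the list alone (camera adjusted p = 0.104, and 0.0432 without vehicle mouse 11). Periportal genes had 3 of 13 higher, also 3 adjusted over the list alone (camera adjusted p = 0.066). Targets of the aryl hydrocarbon receptor and NRF2 had 3 of 10 higher and 2 lower, the same adjusted over the list alone, with a median of -0.09 and a mean of -0.05 where the test pointed upward (camera adjusted p = 0.903).

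For each comparison, 100 splits of the same mice into groups of the same sizes were counted, the real one included. Chance is called excluded, at a share under 0.05 and for a count as a whole, where 1 split, the real one, gave as many genes. Not all possible splits were drawn, so a share under 1 in 100 could not be seen. The real split alone reached its count for acute CORT (222, highest other 14), acute ENZA (180, highest other 3), acute CORT+ENZA against CORT (24, highest other 3) and against ENZA (248, highest other 8). If each chronic mouse counts as independent, the same held for chronic CORT (2401, highest other 125), chronic CORT+ENZA against CORT (1552, highest other 4) and against vehicle (2434, highest other 550). For the differences between the arms the real split also gave the most genes (873, highest other 80, and 179, highest other 20). Those splits mixed the mice within each arm, which removes the effects of both arms. They ask whether there is any effect, not whether the effects differ, so chance is not called excluded for the differences. Chronic mouse numbers run in sets of 3 mice of 1 group, which may share more than their treatment. With 4 sets kept whole there are 3 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes. The highest other gave 83 genes for chronic CORT, and 1 and 36 for chronic CORT+ENZA against CORT and vehicle. For acute CORT+ENZA against vehicle (339) 2 of the 100 splits gave as many, the real one included, a share under 0.05. The highest other gave 645 genes with L19A and L36A on the same side, which points to a structure of the samples. Since such a structure can exceed the real count, chance is not called excluded for this comparison. For the interaction the real count was 0, which all 100 splits reach whatever the data (highest other 3), so the splits say nothing about chance there.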
